A study of Caenorhabditis elegans with 2 samples.

How the data were processed

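Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on whole-worm lysates of wild-type Caenorhabditis elegans fed bacteria that silence spg-7, a gene for a mitochondrial protease. ATFS-1 is a bZIP transcription factor of the mitochondrial unfolded protein response (UPRmt). Per the labels' protocols, eggs were grown on the RNAi food, L4 larvae were harvested after about 48 h, protein and DNA were cross-linked with 11% formaldehyde, and chromatin was sonicated to fragments of 500 to 1000 bp. One library was made with an antibody against ATFS-1 and one without antibody, so each condition has 1 library and there is no replicate. The file header placed the 2 libraries in different sequencing project folders, so the project and the antibody cannot be told apart.

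The one deposited table was a list of peaks that MACS 1.4.2 called on single libraries with the antibody library as ChIP sample and the no-antibody library as control, per the file headers. BWA 0.7.5, Picard and MACS 1.4 are named in the submitters' processing notes. The genome build is not given in the sources used here. Per the file headers, the caller used an effective genome size of 90000000 bp, a p cutoff of 1e-05, a fragment size of 200 bp, 50-bp tags, at most 1 tag per position, and regional background windows of 1000 and 10000 bp, and it scaled the larger library towards the smaller. The antibody library had 18329145 tags, of which 10992796 remained after removal of duplicates (40.0% removed), and the control had 13281029 and 10583049 (20.3% removed), per the file headers. The filtered depths were therefore close, but the antibody library was more redundant.

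For each peak the deposited list gave its position, its length in bp, its summit and the count of antibody tags in the region. It also gave the fold enrichment, a score and a false discovery rate in percent. Fold enrichment is the caller's ratio of antibody signal over the expected control level. It need not equal the tags of the whole region over the tags expected there. The heading of the score column had been replaced by a spreadsheet error in the deposited file. It was read as log10 of the caller's p-value with its sign turned, times 10, because of its place in the caller's column order and because its smallest value, 50.06, lies just above the cutoff of 1e-05 on that scale. In MACS 1.4 the false discovery rate in percent is the number of peaks called with the libraries swapped over the number called as deposited, at the same or a better score. The deposited list also carried a column of gene names, with 1 name at 831 peaks, 2 or more at 100 and none at 74, and a total of 1005, equal to the number of peaks. How the names were assigned is not given in the sources used here. All tag counts, folds, scores and percentages below are those of the authors' peak caller and were used only to describe, rank or filter peaks within the list.

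No genome sequence or strand was used here, so the planned tests of peak position relative to genes and of motifs under summits were not run, and coordinates are those of the deposited list. Gene names were matched to the RefSeq gene table of assembly WBcel235, used only for names, gene classes, chromosomes and gene lengths. A name was accepted only if a gene of that symbol or locus name lay on the peak's chromosome, after removal of comments and letter case. Position along the chromosome was not checked, so an accepted name may not be the gene at the peak. The name rps-6, for example, was accepted at peaks starting at 9625351 and at 13950790 on chromosome I. Of 1033 names, 933 (90.3%) matched, 13 belonged to a gene on another chromosome and 87 had no gene of that name, among them older names such as yme-1 and cco-1. The matched names gave 918 distinct genes, of which 908 were protein-coding.

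Gene lists were fixed before the data were examined. Members whose symbol was not in the gene table were dropped. They were hsp-10 (mitochondrial quality control, 17 given), timm-44 (import, 19 given) and daf-21 (cytosolic heat shock, 16 given). The setting with older names matched by hand did not restore them. Each of the 19 protein-coding lists was tested with Fisher's exact test (two-sided, with the conditional odds ratio and its exact 95% interval) against all other protein-coding nuclear genes of the table, 19971 in all, with Benjamini-Hochberg adjustment over the lists alone. Lists of transfer RNA and small nucleolar and nuclear RNA genes were not tested, because the added names were almost all of protein-coding genes. Peaks per chromosome were to be compared with chromosome length. Lengths in the build of the list were not used here, so an exact two-sided binomial test against the share of protein-coding genes was used, with Benjamini-Hochberg adjustment over the 6 chromosomes. Fold enrichment of a list's peaks was compared with that of random sets of as many peaks (10000 draws, two-sided permutation test) for the 8 lists with at least 5 peaks. This test, the differences between lists and the odds ratios without single genes were chosen after the list was seen. In all of these tests genes or peaks are the units, so the p-values describe this one list and not the variation between worm cultures.

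Genes were named by a rule set in advance: those at the 12 peaks with the highest fold enrichment, then spg-7, atfs-1, hsp-6 and hsp-60, and up to 4 members of each list by fold. A few others outside that rule, chosen after their values were seen, are named where a list had 5 peaks or a peak was shared. So are ppgn-1 and members of the gene families vha and zip. Genes listed under a locus name, such as F15D3.7 for timm-23, are printed by the current symbol. Alternatives covered stricter peak sets, the treatment of gene names, gene length and the background. The list test was run on simulated data of 908 genes drawn from 19971: no list was called in any of 100 sets without enrichment, and oxidative phosphorylation genes given a weight of 6 were called in 96 of 100 sets. Genes were drawn singly, so these sets leave out the dependence between genes named at a shared peak. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.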

Results

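To find genomic sites of ATFS-1 during mitochondrial stress, chromatin from spg-7(RNAi) worms at the L4 stage was precipitated with an ATFS-1 antibody and compared with the same kind of lysate taken through without antibody. The list held 1005 peaks, all on the 6 nuclear chromosomes, and no peak on the mitochondrial genome. Tags on the mitochondrial genome were not analysed here. The caller kept at most 1 tag per position, and called peaks may be missing from the list, so binding there is not excluded. After removal of duplicates the antibody library held 10992796 tags and the control 10583049. The median fold enrichment was 3.26 (quartiles 2.75 and 4.04), 740 peaks (73.6%) lay under 4-fold, 137 reached 5-fold and 11 reached 10-fold. Peaks had a median length of 1555 bp (984 to 11562 bp) and a median of 325 antibody tags (176 to 4741), and together they held 458159 tags, 4.17% of the filtered antibody library. Their summed length was 2.19% of the effective genome size. With 1 library per condition no peak has a replicate check. The caller's own false discovery rate was 7.55% at the median peak and 5% or less for 32 peaks. The rate did not rise steadily as the score fell, so these were not the 32 best-scoring peaks. For example, rpl-12 (score 2101.59) had a rate of 5.56% and aldo-1 (score 1469.19) a rate of 2.78%.

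Of the 12 peaks with the highest fold enrichment, 2 lay at genes of mitochondrial proteostasis, yme-1 and hsp-6, and 10 at other genes. The highest fold enrichment, 13.08 with 728 tags, was at yme-1 (chromosome III, 10415011 to 10416600). The name is an older one for the gene of a mitochondrial inner-membrane AAA protease. hsp-6, the mitochondrial HSP70 chaperone and a standard reporter of the UPRmt, had the fifth highest fold, 11.85 with 2186 tags (chromosome V, 4823219 to 4828158), at a false discovery rate of 0. Others among the 12 highest were hpd-1, an enzyme of tyrosine breakdown (11.61-fold, 1482 tags, chromosome III, 10533024 to 10538186), the anion transporter gene abts-4 (10.19-fold, 1391 tags), the glutaminase gene glna-1, listed as C09F9.3 (10.03-fold, 668 tags), the calmodulin gene cmd-1 (986 tags, rank 11 by fold) and a peak assigned to rpl-15 and K11H12.8 (9.96-fold, 2152 tags). The remaining 5 carried only locus names. They were Y43F8B.2 (12.28-fold, chromosome V, 19520680 to 19523488), B0205.13 (12.21-fold at a false discovery rate of 6.88%, I, 10726178 to 10730242), F19B2.6 (12.12-fold, V, 20157666 to 20162023), H28G03.2 (11.53-fold, X, 5210155 to 5218039) and ZK673.2 (11.31-fold, II, 10444492 to 10448781). The genome build of these coordinates is not given in the sources used here, and whether the peaks lie in promoters, exons or introns was not analysed here.

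**Figure D1:**
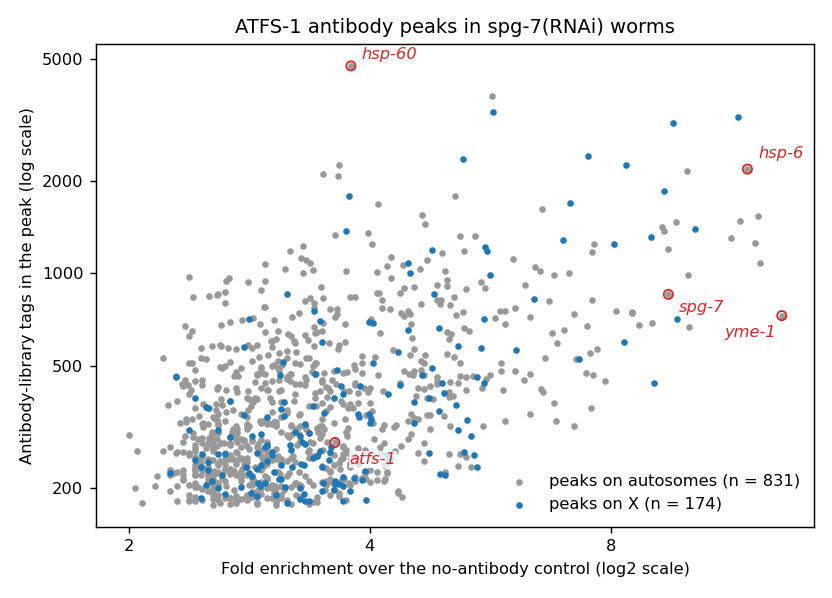
Each point is 1 of the 1005 peaks, placed by its fold enrichment over the no-antibody control (x axis, log2 scale) and its number of antibody tags (y axis, log scale), with X-linked peaks in blue and autosomal peaks in grey; 5 named peaks are circled in red. hsp-6 (11.85-fold) and yme-1 (13.08-fold) lie at the right edge, while hsp-60 has the most tags (4741) at 3.79-fold.

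Of the other genes fixed in advance, spg-7, atfs-1 and hsp-60 each had a peak. spg-7, the RNAi target, had a 9.44-fold peak with 854 tags (chromosome I, 3465746 to 3468451). RNAi food carries plasmid with part of the target gene, and whether this peak falls on that part was not analysed here. hsp-60, the mitochondrial chaperonin, held more tags than any other peak, 4741, but at only 3.79-fold (chromosome III, 1615912 to 1622310), and its false discovery rate was blank in the list. Its tags per kb divided by its fold came to 195, 2.06 times the next highest peak. atfs-1 itself had a small peak of 3.62-fold and 281 tags (chromosome V, 14199688 to 14200873), at a false discovery rate of 7.77%.

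Genes of mitochondrial protein quality control and the UPRmt were named at peaks far more often than other genes. Of 16 such genes, 7 had a peak (odds ratio 16, 95% interval 5.19 to 49.7), against 4.52% of other protein-coding genes. Besides hsp-6, spg-7, hsp-60 and atfs-1 these were the prohibitins phb-1 (4.97-fold, at a peak shared with the ribosomal protein gene rpl-27A) and phb-2 (3.91-fold) and the protease gene ppgn-1 (3.61-fold). Fisher's exact test gave an adjusted p of 1.49e-05. With spg-7, the RNAi target, left out, 6 of 15 had a peak (odds ratio 14.1, 95% interval 4.12 to 44.4). Leaving out hsp-6 or hsp-60 instead gives the same counts by construction, so it is no separate check. The peaks of this list also had higher folds than the rest (mean log2 fold 2.39 against 1.80, permutation test, adjusted p = 0.0432 over 8 lists), and by the same permutation test the mean was 2.19 without hsp-6 (unadjusted p = 0.0658), 2.25 without spg-7 (0.0392) and 2.47 without hsp-60 (0.0044). These values leave yme-1 among the other peaks, because its older name did not match. With older names matched by hand, a choice made after the list was seen, yme-1 was counted in the list, 8 of the 16 genes had a peak (odds ratio 20.8) and the mean log2 fold was 2.55 against 1.80 (permutation test, adjusted p = 0.0016). The unadjusted permutation p was then 0.0036 without hsp-6.

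Mitochondrial import, oxidative phosphorylation and the tricarboxylic acid cycle followed, with 27.8%, 24% and 23.8% of their genes at peaks. Of 18 import genes 5 had a peak (odds ratio 8.11, 95% interval 2.26 to 24.3), led by timm-23, the inner-membrane channel (7.57-fold, 1174 tags), timm-17B.1 (5.0-fold), tomm-7 (4.25-fold) and tomm-20 (2.55-fold). Of 50 nuclear oxidative phosphorylation genes 12 had one (odds ratio 6.70, 95% interval 3.18 to 13.2). cyc-2.1, a cytochrome c gene, stood highest at 9.66-fold and 1467 tags, followed by the complex I gene nduf-6 (4.63-fold, at a peak shared with nrs-1), the ATP synthase gene atp-3 (4.49-fold) and sco-1, a cytochrome c oxidase assembly factor (3.87-fold). Of 21 genes of the cycle and of pyruvate entry 5 had one (odds ratio 6.59, 95% interval 1.88 to 18.9): aco-2, aconitase (4.69-fold, 1451 tags), sucl-1 (3.96-fold), cts-1, citrate synthase (2.96-fold), dlst-1 (2.89-fold) and pyc-1 (2.52-fold). The adjusted p-values by Fisher's exact test were 0.00318, 1.13e-05 and 0.00505 in that order. The tricarboxylic acid cycle passed no longer with only the 504 peaks at or above the median fold (adjusted p = 0.164 by Fisher's exact test; 0.000895 to 1 over the settings tried).

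Mitochondrial ribosomal protein genes did not pass the test. Only mrpl-37 (2.81-fold) and mrpl-20 (2.65-fold) of 71 had a peak (odds ratio 0.608, 95% interval 0.0720 to 2.29, adjusted p = 0.864 by Fisher's exact test). The difference from oxidative phosphorylation genes, 12 of 50 against 2 of 71, passed Fisher's exact test (odds ratio 10.7, 95% interval 2.21 to 103, adjusted p = 0.00300 over 8 such differences), as did that from cytosolic ribosomal protein genes, 21 of 78 (odds ratio 0.0798, 95% interval 0.00871 to 0.349, adjusted p = 0.000211). Neither passed with the 32 peaks at a false discovery rate of 5% or less, where no mitochondrial ribosomal protein gene was at a peak (exact test, adjusted p = 0.826 and 1).

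Glycolytic genes had the highest share at peaks of any list tested, 11 of 19 (odds ratio 29.2, 95% interval 10.7 to 83.8, adjusted p = 8.31e-10 by Fisher's exact test). A single 7.5-fold peak of 2419 tags was assigned to the glyceraldehyde-3-phosphate dehydrogenase genes gpd-2 and gpd-3 and to mai-1 between them in the listed order (chromosome X, 3111880 to 3117019). The gpd genes are near-identical copies counted as 2 of the 11, so this part of the count is uncertain. The lactate dehydrogenase gene ldh-1 followed at 7.09-fold, ipgm-1, phosphoglycerate mutase, at 6.76-fold, and the aldolase gene aldo-1 at 5.19-fold. Among the 32 peaks with a false discovery rate of 5% or less glycolysis alone of the 19 lists passed, with older names left unmatched. It passed on 3 genes at 2 peaks, namely gpd-2 and gpd-3 at their shared peak and aldo-1. With gpd-2 and gpd-3 counted as 1 gene, 2 of 18 remained there (odds ratio 95.4, Fisher's exact test, adjusted p = 0.00544), and 10 of 18 among all peaks (odds ratio 26.5, exact test, adjusted p = 1.06e-08). The yme-1 peak, at a rate of 4%, was also among the 32, but its older name was not matched. Older names were not tried with those 32 peaks, so whether mitochondrial quality control would then pass was not tested.

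Peaks were not limited to mitochondrial and glycolytic genes. Of 17 genes of the endoplasmic reticulum stress response 7 had a peak (odds ratio 14.8, 95% interval 4.77 to 43.2, Fisher's exact test, adjusted p = 1.94e-05). Among them were the stress kinase gene pek-1 (9.68-fold), the chaperone gene hsp-3 (4.74-fold), pdi-3 (3.99-fold) and the transcription factor gene atf-6 (3.70-fold). Of 78 cytosolic ribosomal protein genes 21 had a peak (odds ratio 7.89, 95% interval 4.52 to 13.3, Fisher's exact test, adjusted p = 4.57e-10), led by rpl-15, rpl-12 (9.26-fold), rpl-35 (7.44-fold) and rpl-3 (7.20-fold). Set against these ribosomal genes, the lists of mitochondrial quality control, import, oxidative phosphorylation, the tricarboxylic acid cycle and endoplasmic reticulum stress had odds ratios of 0.850 to 2.09, none past Fisher's exact test (adjusted p = 0.406 to 1), although mitochondrial quality control passed with peaks at or above the median fold (odds ratio 4.63, exact test, adjusted p = 0.0239; 0.0239 to 0.826 over the settings tried). For glycolysis the odds ratio was 3.67 (95% interval 1.17 to 12.1, Fisher's exact test, adjusted p = 0.0387), but this was not past the threshold with gpd-2 and gpd-3 counted as 1 gene (3.34, adjusted p = 0.0700) or with older gene names matched by hand (2.88, adjusted p = 0.164). Its adjusted p ran from 0.00832 to 0.714 over the settings tried. Of 72 histone genes 10 had one (odds ratio 3.41, 95% interval 1.55 to 6.73, Fisher's exact test, adjusted p = 0.00405). Most were named in pairs at a shared peak, such as his-61 with his-62 (3.57-fold) and his-35 with his-41 (3.30-fold), and histone copies are near-identical, so this count is uncertain. his-72 (3.50-fold) shared its peak with rpt-6, and his-24 (3.32-fold) had a peak of its own. When only peaks with 1 gene name were counted, the histone odds ratio turned to 0.365.

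**Figure D2:**
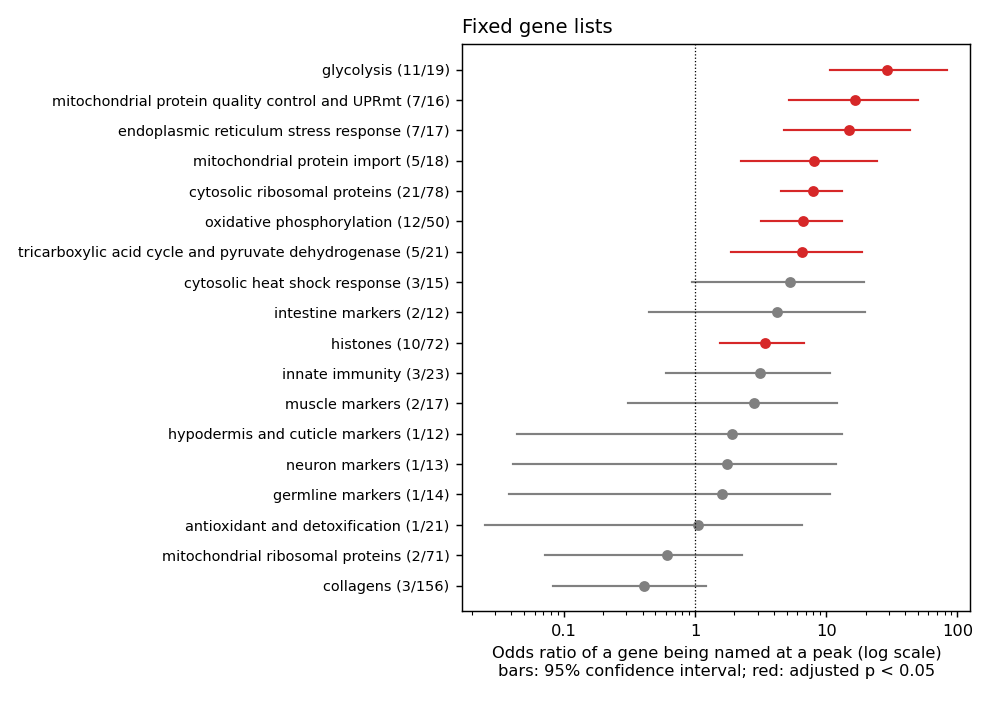
Odds ratio that a gene of each fixed list was named at a peak, relative to all other protein-coding genes (x axis, log scale), with 95% confidence intervals and the number of list genes at peaks over the number in the list; red marks an adjusted p below 0.05, and vitellogenins (0 of 6) are not drawn. Glycolysis (11 of 19) is highest, and mitochondrial ribosomal proteins (2 of 71) and collagens (3 of 156) lie below 1 with intervals that include it.

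The other lists did not pass the test. Cytosolic heat shock genes were at 3 of 15 (Fisher's exact test, adjusted p = 0.0598), namely hsp-1 (5.11-fold), dnj-12 (2.93-fold) and sti-1 (2.05-fold). Over other settings the adjusted p of this list by exact or permutation tests ran from 0.0319 to 0.475, passing with lists matched on gene length and with single-name peaks. Innate immunity genes were at 3 of 23 (Fisher's exact test, adjusted p = 0.160), namely tir-1 (6.56-fold), zip-2 (4.40-fold) and hlh-30 (3.47-fold). This list passed with the 503 peaks at or above the median score (exact test, adjusted p = 0.0353) and with those at or above the median fold (0.0382), in a range of 0.0353 to 0.263 over the settings tried. Of 21 antioxidant and detoxification genes only skn-1, the regulator of that response, had a peak (6.69-fold, Fisher's exact test, adjusted p = 1). Collagens were at 3 of 156 (Fisher's exact test, adjusted p = 0.262), with col-103 at 2.58-fold, col-85 at 2.41-fold and col-71 at 2.21-fold. Vitellogenins, the yolk proteins, were at 0 of 6 (upper 95% limit of the odds ratio 17.8). Markers of tissues in the whole-worm lysate had few peaks: 2 of 17 for muscle (myo-2, 3.10-fold; act-2, 3.07-fold), 2 of 12 for intestine (fat-6, 3.78-fold; asp-1, 3.20-fold), 1 of 14 for germline (glh-4, 2.83-fold), 1 of 13 for neurons (snb-1, 2.81-fold) and 1 of 12 for hypodermis (dpy-13, 262 tags). Their odds ratios were all above 1, from 1.62 for germline to 4.21 for intestine. Their adjusted p-values by Fisher's exact test ran from 0.174 to 0.569, and with so few genes their intervals do not exclude large odds ratios (upper limits 10.8 to 19.8).

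Peaks were spread unevenly over the chromosomes relative to genes. Chromosome III carried 187 peaks, 18.6% of the list (95% exact interval 16 to 21.2) against 13.2% of protein-coding genes. Chromosome V carried 161, 16.0% (13.8 to 18.4) against 25% of genes. Chromosomes I (179 peaks) and X (174) were above their gene shares by 1.24 and 1.27 times, chromosome II (139) was at 0.802 times its share, and chromosome IV (165) was at 0.999. Exact binomial tests gave adjusted p-values of 4.55e-06 for III, 3.67e-11 for V, 0.00219 for X and 0.00416 for both I and II. The excess on I was not past the threshold among the 503 peaks at or above the median score (1.21 times, exact binomial test, adjusted p = 0.0677) or among those at or above the median fold (1.01 times, adjusted p = 1), and its adjusted p ran from 0.00416 to 1 over the settings tried. Among the 32 peaks with a false discovery rate of 5% or less only X passed (3.20 times its gene share, exact binomial test, adjusted p = 0.000196; 1.04e-06 to 0.0375 over the settings tried). By the same exact test III (1.18 times, adjusted p = 0.726), V (0.50 times, 0.451) and II (0.543 times, 0.522) had their highest adjusted p-values of the settings tried among these 32 peaks, and I turned to 0.434 times its share (0.522).

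**Figure D3:**
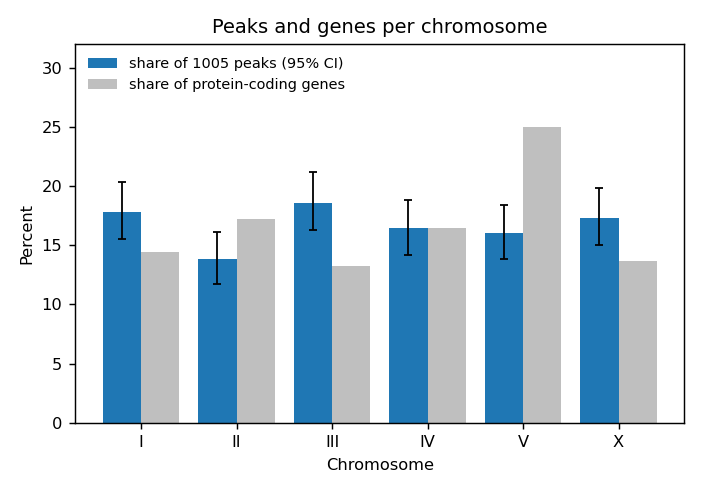
Share of the 1005 peaks (blue, with exact 95% binomial intervals) and of protein-coding genes (grey) on each nuclear chromosome, in percent. The shares differ most on chromosome V (16.0% of peaks, 25% of genes) and chromosome III (18.6% and 13.2%).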

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

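No paired analysis was possible because each condition has 1 library, and no library could be left out. Not run, for want of strand and a genome in the coordinates of the list, were promoter windows, peak overlap, nearest 5′ ends, random placement along chromosomes, peak midpoints, motif windows and backgrounds, and chromosome length. Older names, symbols only, single-name peaks, 2 peaks with odd false discovery rates left out, gene length, gpd-2 and gpd-3 counted as 1 gene, the pooling of mitochondrial lists and the differences between lists were chosen after seeing the data. Of the 1005 peaks, 32 had a false discovery rate of 5% or less and 137 a fold of at least 5. With those 32 peaks, 1 of the lists (glycolysis, odds ratio 143, from 3 genes at 2 peaks because gpd-2 and gpd-3 share 1) and 1 chromosome (X, 3.20 times its gene share) passed. The yme-1 peak, at a rate of 4%, was among the 32 but was not counted, because its older name was unmatched. Older names were not tried with those 32 peaks. There the odds ratios were 47.3 for mitochondrial quality control and the UPRmt, 41.8 for import, 14.5 for oxidative phosphorylation and 9.21 for cytosolic ribosomal proteins, none past the threshold (49.1, 43.3, 15.03 and 9.55 with gpd-2 and gpd-3 counted as 1 gene, and glycolysis, the 1 list past it, 95.4), and chromosome I turned to 0.434 times its gene share. They were 0, the other side of 1, for the tricarboxylic acid cycle, endoplasmic reticulum stress, histones, antioxidant genes and the muscle, intestine, germline, neuron and hypodermis markers; few peaks remain by construction. Germline, neuron and hypodermis markers also fell to 0 with peaks at or above the median score or the median fold, muscle markers with the latter, and germline markers with single-name peaks. With peaks at or above the median fold the tricarboxylic acid cycle no longer passed (odds ratio 4.39). Innate immunity passed with the same peaks (6.27) and at or above the median score (6.17), and heat shock with single-name peaks (6.52) and gene length (5.62 times the number expected); the cause was not tested. With single-name peaks histones reversed (0.365), since that choice drops the histone pairs, and with symbols only antioxidant genes did (0.762; the cause was not tested). Relative to cytosolic ribosomal proteins, none past the threshold in either case, import turned to 0.817 with older names, oxidative phosphorylation to 1.57 with the 32 peaks and 1.25 with single-name peaks, the tricarboxylic acid cycle to 1.02 at or above the median score and 1.55 with single-name peaks, and endoplasmic reticulum stress to 0 with the 32 peaks; the cause was not tested. Glycolysis against these genes was not past the threshold with the 32 peaks (13.9, or 9.29 with gpd-2 and gpd-3 as 1 gene), older names (2.88) or gpd-2 and gpd-3 as 1 gene (3.34). Oxidative phosphorylation against mitochondrial ribosomal proteins gave no finite value where no gene of the latter was at a peak. Apart from the 32 peaks, 8 or 9 lists passed under each setting, and the pooled mitochondrial value lay between 3.36 and 5.30 (13.2 and 13.7 with the 32 peaks). No listed peak had under 176 tags, a minimum that depends on the caller's cutoff as well as on depth, and what depth limits was not tested.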

Other observations

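Chosen after the list was seen were the pooling of mitochondrial lists (before any list was tested) and the tests of gene families, of differences between lists, of symbols only and gene length, of hsp-60, of X-linked and unnamed peaks, and of the false discovery rates. Among 183 gene families defined by a shared symbol prefix with at least 10 protein-coding members, 9 were named at peaks more often than other genes and 2 less often (two-sided Fisher's exact test, Benjamini-Hochberg over families). Besides rpl, rps and his, the enriched families were the vacuolar proton pump genes vha (8 of 20, odds ratio 14.1, 95% interval 4.99 to 37.6, Fisher's exact test, adjusted p = 0.000125), the DnaJ co-chaperones dnj (8 of 29, odds ratio 8.06) and the ubiquitin-conjugating enzymes ubc (6 of 21, odds ratio 8.44). The others were pqn (9 of 55), lin (8 of 47) and the bZIP transcription factors zip (4 of 12, odds ratio 10.5, 95% interval 2.32 to 39.4, Fisher's exact test, adjusted p = 0.0261). Among the pump genes vha-12 had a 3.87-fold peak, and vha-3 and vha-11 shared one at 3.06-fold. The zip genes were zip-3 (5.41-fold, 1320 tags), zip-2 (4.40-fold), zip-12 (3.44-fold) and zip-11 (3.40-fold).

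The 2 families named less often had no named peak. They were the C-type lectin genes clec (0 of 239, upper 95% limit of the odds ratio 0.323, Fisher's exact test, adjusted p = 0.00119) and the chemoreceptor genes str (0 of 193, upper limit 0.402, Fisher's exact test, adjusted p = 0.00581). Nuclear hormone receptor genes (nhr) were at 16 of 269 (odds ratio 1.33, 95% interval 0.747 to 2.22, Fisher's exact test, adjusted p = 0.857).

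The lists of mitochondrial proteins, pooled over 5 lists, had 31 of 176 genes at peaks (odds ratio 4.61, 95% interval 3.00 to 6.88). How the names were assigned is not given, and they may favour familiar genes. With hits and background limited to genes with a symbol the odds ratio was 3.36 (2.19 to 5.03). This argues against a preference for genes with a symbol as the whole cause. A symbol does not measure how familiar a gene is, so a preference for familiar genes stays open. Gene length is also argued against, since 0 of 10000 random lists matched on length reached 31 genes (mean 7.15, highest 17). Signal at strongly transcribed genes of any kind stays open: the odds of a peak over those of cytosolic ribosomal protein genes were 0.580 (0.308 to 1.09), a value lowered by the mitochondrial ribosomal proteins, and 1.04 (0.511 to 2.12) for the other 4 lists (29 of 105 against 21 of 78). Transcription was not measured here, and cytosolic ribosomal protein genes were the only stand-in used for strongly transcribed genes. Binding of ATFS-1 itself, the antibody's target, also stays open and was not tested.

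The hsp-60 peak combined the most tags in the list with a fold of only 3.79. Several peaks merged by hand stay open: the peak held 741 tags per kb, 1.57 times the densest other peak (471), so a merged part would itself have to be denser than any other peak, which the list does not exclude. Extra copies of the hsp-60 region in the DNA of both libraries also remain a possible explanation that these data do not decide. Its tags per kb divided by its fold, 195 or 2.06 times the next highest peak (94.9, at col-71), are built from the same tags and fold and give no independent support. That quotient is not the control level, since the fold need not be formed from the tags of the whole region. No biological explanation was tested.

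Peaks on the X had higher folds than autosomal peaks (medians 3.565 and 3.19, mean log2 difference 0.16, permutation p = 2e-05 with 100000 permutations), and 33 of 174 X-linked peaks had no gene name against 41 of 831 elsewhere (19.0% and 4.93%, Fisher's exact p = 9.86e-09). The unnamed peaks do not account for the fold, as the difference was 0.154 (permutation p = 0.00031) without them. A lower expected level on the X stays open, as control tags were not analysed here. Median tags per kb on the X were 1.03 times those on autosomes (95% bootstrap interval 0.992 to 1.06). This ratio cannot decide the question, because the fold need not be formed from the tags of the whole region. Tags per kb divided by fold, 0.924 times the autosomal median on the X (58.7 and 63.5), are built from the same tags and fold and give no independent support. No biological explanation was tested.

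The false discovery rates were compared with ratios of whole numbers. Of the 80 best-scoring peaks, 15 had a rate of 0, which fits any rank. Of the other 65, 63 had a rate that equalled, within 0.0051 percentage points, a whole number of swapped-library peaks over one of the next 6 ranks by score. Reading the smallest rank that fits at each peak, place 80 corresponds to rank 86 with 5 swapped peaks, with 8 ranks skipped on the way. One of these, rank 11, falls to B0205.13, and 7 belong to no peak of the list under that reading. This reading was adopted after a wider search had given no unique number, so larger numbers are not excluded, and deeper ranks were not determined. The 2 peaks without such a ratio were B0205.13, at 6.88% between peaks at 0 by score, for which ranks far from its place were not tried, and hsp-60, with no rate. The peaks on either side of hsp-60 by score held the consecutive ranks 55 and 56, so no rank was free at its place.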
